A study of Arabidopsis thaliana with 6 samples.

How the data were processed

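The study measured gene expression by RNA sequencing in 6 samples of *Arabidopsis thaliana*, 3 labelled *smxl4 smxl5* and 3 labelled wild type in the shoot. Per the labels' protocols, seedlings were grafted onto wild-type roots, RNA came from 1 cm of the stem base, 3 fragments were pooled per biological replicate, and libraries were made from polyadenylated RNA with a directional kit and 12 cycles of amplification. Samples were grouped by the genotype of the analysed stem given in the labels, and replicate numbers come from the sample titles. The description of each wild-type sample gives replicate 1, unlike the titles, while the protocol states 3 biological replicates per genotype. The wild-type samples were counted as 3 on that statement, which the counts cannot check.

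The authors deposited raw read counts per gene for each sample, with locus codes as gene names. Per the submitters' processing notes, FastQC 0.11.7, TopHat2 2.0.14, DESeq2 and the TAIR10 build were used. The program that counted the reads, its strand setting and its annotation are not given in the sources used here, so reads of overlapping or antisense genes may have been assigned to either. The authors also deposited a comparison table with, per the file headers, a mean of normalized counts (signal), a log2 fold change with its standard error, a test score and a p-value with its adjusted value. The sign of the deposited log2 fold change was found from the counts to be wild type over mutant, and its values are shrunken towards 0. The mean column equals the mean of the deposited counts over size factors recomputed here. The deposited score column was not used in any comparison.

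Gene names, coordinates, exon lengths and GC content were taken from the RefSeq annotation of TAIR10.1, where 32835 of the 33602 loci of the count table were found, as were 20101 of the 20296 tested. Library totals ran from 21364628 to 49929595 counts. The 18S ribosomal RNA genes took between 0.532% and 1.09% of counts and the 10 most abundant genes between 5.23% and 6.33%. Replicates of a group differed by 12.7 to 38.0 in chi-square per gene, well above sampling noise, so no library repeats the reads of another.

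The main test was edgeR 4.0.16 in R 4.3.3 on the deposited counts, with genes kept by filterByExpr (minimum count 10, minimum total 15), TMM factors, robust quasi-likelihood fits, a two-sided quasi-likelihood F test of genotype and Benjamini-Hochberg adjustment over all genes tested at 0.05. Fold changes are log2 of mutant-labelled over wild type, with a prior count of 0.125, and standard errors were taken as the fold change over the square root of F. CPM values use the TMM-scaled library sizes. The design names genotype only, and adjusted p-values in the text are from edgeR unless another tool is named.

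Gene lists were fixed before the data were examined. There were 21 lists with 398 members, of which 390 had a symbol or synonym in the annotation that matches the code and 8 were kept by code alone. They covered phloem regulators, sieve element and companion cell function, cambium, xylem and secondary wall, lignin, cell division, strigolactone and karrikin signalling, anthocyanin and flavonoid synthesis, starch, sugar starvation, photosynthesis, epidermis and cuticle, root tissues, suberin and periderm, floral organs, jasmonate, salicylate and immunity, abscisate and dehydration, auxin response, cytokinin response and glucosinolate. Each list was tested with camera from limma 3.58.1, two-sided, at a preset inter-gene correlation of 0.01 and with an estimated correlation, adjusted over all lists. With an estimated correlation camera takes its degrees of freedom from the few libraries rather than from the genes. That alone raises p, whatever the size of the correlation. Of 10 lists that passed at the preset correlation, 0 passed with an estimated one, where 6 had an unadjusted p under 0.05 and the lowest adjusted p was 0.145. In fry, 10 lists moved one way on balance and 19 changed in either direction. Beside each count of called members the text gives the count adjusted over the list alone. List deviations per library are means of log2(CPM + 0.5) relative to the mean over all libraries.

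The rule for named genes was also fixed before the data were examined. It took *SMXL3*, *SMXL4* and *SMXL5*, then the 8 largest rises and the 8 largest falls among called genes with a mean of at least 1 CPM and no overlap between groups, and from the lists the called members with the largest fold changes, 4 from each phloem list and 2 from each other list, filled up with the most abundant members. The value of 1 gene taken by the rule is not reported here. Other genes named in the text are said to have been singled out after their values were seen. Named loci were searched with BLAST 2.17.0 against all annotated transcripts for stretches of at least 95% identity over at least 200 bases. Of the 62 loci, 17 overlap another annotated locus on the opposite strand and 2 on the same strand.

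The scripts were tested on simulated counts for this comparison with changed genes of known size over 20171 genes. edgeR recovered 31.8% of genes changed by 0.5, 77.6% of those changed by 1 and 98.5% of those changed by 2 on the log2 scale, with 8.84% false calls among its calls. It called 181 genes there and 5053 in the data, so these shares need not hold for the data. Of 20 unmoved lists 0 were called, and the moved list was found with both correlations. Genes were drawn independently in the simulation, while the photosynthesis list, for example, had an estimated correlation of 0.60 in the data. The simulation therefore does not check the preset correlation for lists whose members vary together.

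The alternatives chosen before the data were examined were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, no filter and a stricter filter (at least 1 CPM in 3 samples), non-robust fits, camera on limma-voom values, fry, an adjusted p of 0.01, a minimum log2 fold change of 1, the replicate number as a block, and leaving out each library. Thinning of all libraries to the smallest total was chosen after seeing the data. The closing section gives their effect. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.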

Results

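RNA sequencing counts were collected from the base of *Arabidopsis thaliana* inflorescence stems labelled *smxl4 smxl5*, after a pair of related SMXL genes known to promote phloem formation, or wild type. The shoots of both genotypes grew on wild-type roots attached by grafting, so that the genotypes differed above the graft. Each genotype had 3 libraries, and each library pooled 3 stem fragments of 1 cm taken from plants 15 to 20 cm tall. The libraries labelled *smxl4 smxl5* held 32997321, 21364628 and 36133200 counts over genes, and those labelled wild type held 33749559, 45403651 and 49929595. Of 33602 genes in the table, 26258 had at least 1 count and 20296 were tested.

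The comparison asked which genes differ at the base of a radially growing stem between *smxl4 smxl5*, which the study describes as defective in phloem, and wild type. The genes named by the genotype were examined first. *SMXL4* (AT4G29920; TAIR10.1 chromosome 4, 14632413 to 14636101) reached 13.4, 15.3 and 11.2 CPM (read counts scaled to library size) in the libraries labelled *smxl4 smxl5* (mutant-labelled) and 12.1, 10.2 and 11.1 CPM in wild type. Its log2 fold change was 0.26 ± 0.13 (SE), with an adjusted p of 0.179 from edgeR's quasi-likelihood test. Without mutant-labelled replicate 3 it was 0.37 and passed the threshold (edgeR adjusted p = 0.0490). *SMXL5* (AT5G57130; chromosome 5, 23144947 to 23149615) reached 116, 116 and 82.0 CPM against 112, 97.5 and 99.4 CPM, a log2 fold change of 0.02 ± 0.14 (edgeR adjusted p = 0.920). Their relative *SMXL3* had a log2 fold change of -0.24 ± 0.14 (edgeR adjusted p = 0.243). Neither targeted gene was lower, so these counts do not check the genotype labels. The labels do not describe the alleles, and a count summed over a whole gene cannot show whether its transcript is interrupted. All directions are therefore those of the mutant-labelled libraries relative to the libraries labelled wild type.

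In the mutant-labelled libraries 13 of 26 phloem regulators, 14 of 28 cambium regulators, 26 of 37 xylem genes, 21 of 31 cell division genes and 28 of 29 photosynthesis genes fell, while 5 of 16 jasmonate and 5 of 20 glucosinolate genes rose. Of 21 lists, 8 were lower and 2 higher in the camera test at a preset correlation, while 0 passed with an estimated correlation, where 6 had an unadjusted p under 0.05 (lowest adjusted p = 0.145 with an estimated correlation). Among called genes with a mean of at least 1 CPM and no overlap between groups, the sugar exporter genes *SWEET11* and *SWEET12* rose most, by 4.48 and 4.44 on the log2 scale. In all, 5053 genes passed an adjusted p of 0.05 in edgeR's test, 24.9% of those tested, of which 2282 were higher and 2771 lower. A fold change of at least 1 on the log2 scale was reached by 387 of the higher and 590 of the lower genes. The 2 groups of 3 libraries did not overlap for 5044 of the called genes and for 45.3% of all genes tested, where chance gives 10%. The median SE of a log2 fold change was 0.11. The first principal component, with 59.8% of the variance, separated the genotypes, and the second, with 17.7%, set mutant-labelled replicates 2 and 3 apart from each other, at 31.8 and -40.1. Fewer libraries lower the power to call genes, and the number of calls moved by more than 1.5 times without some libraries. It was 2510 without mutant-labelled replicate 1 (1012 higher, 1498 lower), 2434 without wild type replicate 1 (884 higher, 1550 lower) and 1902 without wild type replicate 2 (597 higher, 1305 lower). The higher genes also numbered 1512 without mutant-labelled replicate 2.

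Among the regulators of phloem formation, 13 of 26 tested genes fell and 0 rose. *DOF6* (AT3G45610), which encodes a DOF-type transcription factor, fell from 3.56 ± 0.10 CPM (SD, n = 3) to 0.881 ± 0.20 CPM, a log2 fold change of -2.04 ± 0.19 (edgeR adjusted p = 0.00174). The NAC transcription factor genes of sieve element differentiation fell as well. *NAC086* changed by -1.83 ± 0.28, *NAC057* by -1.35 ± 0.20 and *NAC045* by -1.29 ± 0.29 on the log2 scale, with edgeR adjusted p of 0.00575, 0.00547 and 0.0185. The call of *NAC045* was lost without mutant-labelled replicate 1, wild type replicate 1 or wild type replicate 2. It was also lost with the replicate number as a block. The edgeR adjusted p in these settings reached up to 0.0826. *APL*, a regulator of phloem identity singled out after its values were seen, changed by -0.95 ± 0.16 (edgeR adjusted p = 0.00694). The median of the list was -0.46. Adjusted over the list alone, 19 members fell and 1 rose, the latter being *MAKR5* at 0.45 ± 0.16. The list was lower than other genes in the camera test, with an adjusted p of 1.27e-07 at a preset correlation, but the adjusted p was 0.145 with an estimated correlation. Without wild type replicate 2, 7 members fell.

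Among 20 tested genes of sieve element and companion cell function, 13 fell and 4 rose, and the same numbers passed when adjusted over the list alone. *SWEET13*, a sugar transporter gene, fell by 2.24 on the log2 scale (SE 0.48) and *PP2-A2*, a phloem lectin gene, fell by 2.09 (SE 0.19), with edgeR adjusted p of 0.0156 and 0.00168. The call of *SWEET13* was lost without wild type replicate 2 (adjusted p = 0.0636). Singled out after their values were seen, the sieve element occlusion genes *SEOR1* and *SEOR2* changed by -1.43 ± 0.13 and -1.75 ± 0.13, and *SUC2*, the companion cell sucrose loader, went from 158 ± 9.74 to 89.3 ± 11.8 CPM (SD, n = 3). *SWEET11* (AT3G48740; chromosome 3, 18052466 to 18054832) and *SWEET12* (AT5G23660; chromosome 5, 7971647 to 7973995), which encode sucrose exporters of phloem parenchyma, moved the opposite way. *SWEET11* went from 0.333 ± 0.12 to 7.43 ± 1.28 CPM, 22.3-fold (log2 4.48 ± 0.27, edgeR adjusted p = 0.000519), and *SWEET12* from 0.488 ± 0.073 to 10.7 ± 2.69 CPM, 21.7-fold (log2 4.44 ± 0.25, edgeR adjusted p = 0.000398). The other risers were *NAKR1*, needed for phloem long-distance transport, at 0.59 ± 0.12, and *CHER1*, a choline transporter gene of sieve plate development, at 0.30 ± 0.06. The list had a median log2 fold change of -0.76 and a camera adjusted p of 4.00e-06 at the preset correlation, with an adjusted p of 0.145 with an estimated correlation. Without wild type replicate 2, 2 members rose.

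**Figure D1:**
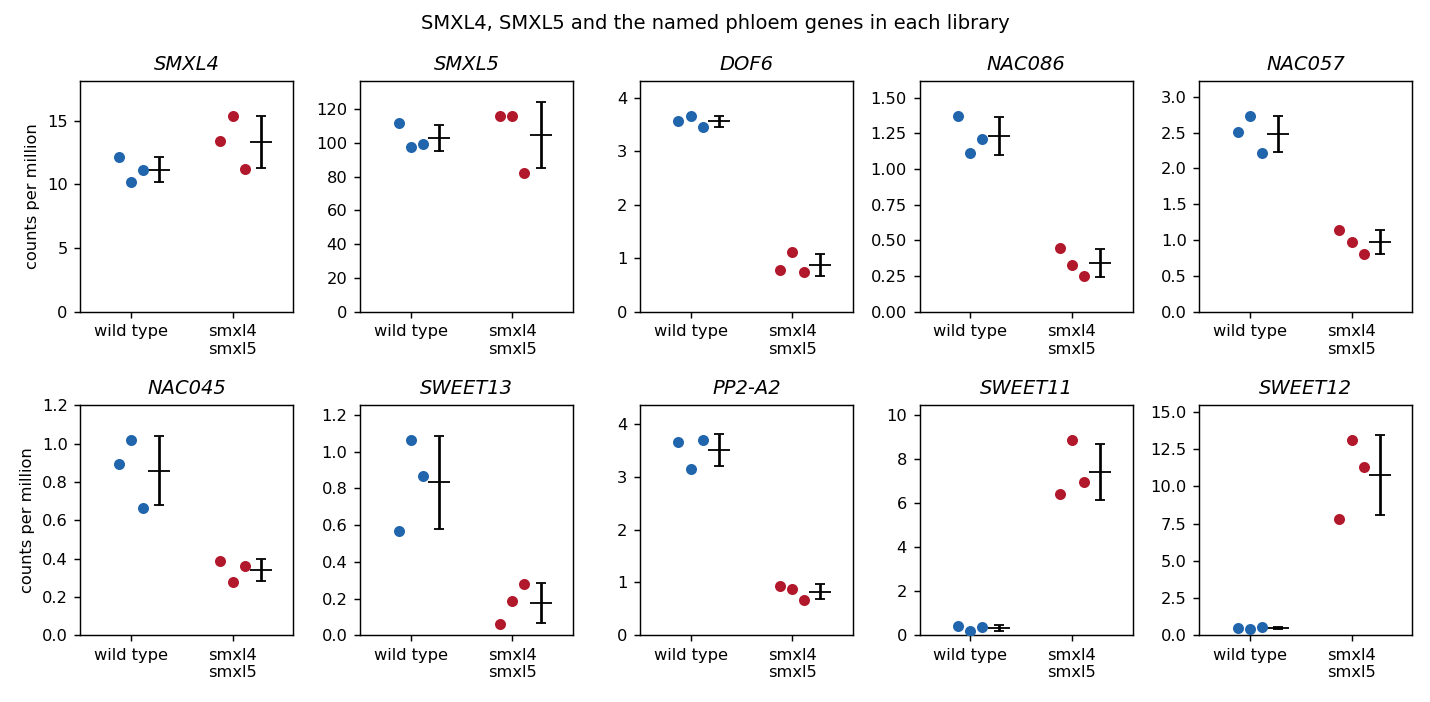
Expression in CPM of *SMXL4*, *SMXL5* and 8 named phloem genes in each library, with 1 point per library and the mean and SD of the 3 libraries beside them (blue, labelled wild type; red, labelled *smxl4 smxl5*). *SMXL4* and *SMXL5* overlap between genotypes, *DOF6*, *NAC086*, *NAC057*, *NAC045*, *SWEET13* and *PP2-A2* are lower and *SWEET11* and *SWEET12* are higher in every library labelled *smxl4 smxl5*.

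The lists that describe radial growth were also lower. Of 28 cambium regulators, 14 fell and 0 rose (16 fell and 0 rose adjusted over the list alone), with a median of -0.36. The LOB-domain genes *LBD1* and *LBD11* fell by 1.88 and 1.05 on the log2 scale (SE 0.28 and 0.10, edgeR adjusted p = 0.00552 and 0.00193). *WOX4*, *PXY* and *ANT*, cambium regulators singled out after their values were seen, changed by -0.52 ± 0.09, -0.37 ± 0.11 and -0.93 ± 0.08. The camera adjusted p of the list was 1.02e-07 at the preset correlation and the adjusted p was 0.145 with an estimated correlation. The number of members that fell was 9 without mutant-labelled replicate 1 and 8 without wild type replicate 2. Of 31 cell division genes, 21 fell and 0 rose (26 and 0 adjusted over the list alone), with a median of -0.70. The mitotic kinase gene *AUR1* changed by -1.05 ± 0.22 and the cyclin-dependent kinase gene *CDKB1;2* by -1.02 ± 0.15, with edgeR adjusted p of 0.0140 and 0.00480. Without wild type replicate 1 the call of *AUR1* was lost (adjusted p = 0.0536). For this list the camera adjusted p was 3.51e-11 at the preset correlation and the adjusted p was 0.217 with an estimated correlation.

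Of 37 genes of xylem and secondary wall formation, 26 fell and 0 rose (30 and 0 adjusted over the list alone), with a median log2 fold change of -0.74. *MYB63*, an activator of lignin genes, went from 35.9 ± 3.54 to 13.6 ± 1.88 CPM (log2 -1.40 ± 0.12, edgeR adjusted p = 0.00150). The NAC factor gene *SND2* went from 102 ± 7.75 to 47.3 ± 6.07 CPM (log2 -1.11 ± 0.11, edgeR adjusted p = 0.00210). Of 18 lignin biosynthesis genes, 14 fell and 0 rose (15 fell and 1 rose adjusted over the list alone), with a median of -0.53. The laccase gene *LAC17* changed by -1.30 ± 0.12 and the phenylalanine ammonia-lyase gene *PAL4* by -0.96 ± 0.17, with edgeR adjusted p of 0.00170 and 0.00894. Camera gave adjusted p of 1.04e-21 for xylem and 1.73e-09 for lignin at the preset correlation, and for each list the adjusted p was 0.145 with an estimated correlation. Without wild type replicate 1, and likewise without wild type replicate 2, 9 lignin genes fell, and 1 rose without wild type replicate 3.

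Markers of other tissues that a stem fragment can hold were followed in the same way. Of 29 photosynthesis genes, 28 fell and 0 rose (29 and 0 adjusted over the list alone), with a median of -0.69. The carbonic anhydrase gene *CA1* fell furthest, by 2.49 on the log2 scale (SE 0.24), and the Rubisco small subunit gene *RBCS3B* went from 549 ± 67.8 to 220 ± 24.1 CPM (log2 -1.32 ± 0.12), with edgeR adjusted p of 0.00276 and 0.00172. The camera adjusted p was 7.34e-30 at the preset correlation and the adjusted p was 0.145 with an estimated correlation. Of 16 epidermis and cuticle genes, 5 fell and 0 rose, the same adjusted over the list alone, with a median of -0.39. They included the wax biosynthesis genes *MAH1* at -2.18 ± 0.24 and *CER1* at -1.90 ± 0.21 (edgeR adjusted p = 0.00374 and 0.00395). Here the camera adjusted p was 1.96e-05 at the preset correlation and the adjusted p was 0.371 with an estimated correlation. In this list mutant-labelled replicate 3 stood apart, with a mean log2 deviation of 0.003 from the mean of all libraries where replicates 1 and 2 were at -0.57 and -0.55. Wild type replicate 3 was also closer to that mean, at 0.10, where wild type replicates 1 and 2 were at 0.42 and 0.59. Without mutant-labelled replicate 3, 8 members fell and the median was -0.79. Without wild type replicate 3, 10 fell, and without mutant-labelled replicate 2 the median was -0.22.

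Of 13 suberin and periderm genes 5 were tested, of which 3 fell and 1 rose, the same adjusted over the list alone, with a median of -0.70 and a camera adjusted p of 0.0585 (0.242 with an estimated correlation). The fatty acyl reductase gene *FAR5*, at 6 counts in total in the mutant-labelled libraries, fell by 3.32 (SE 0.47), and *KCS2* fell by 0.84 (SE 0.10). The riser lost its call without wild type replicate 2. The list test passed without mutant-labelled replicate 3 (adjusted p = 0.0297) and without wild type replicate 1 (adjusted p = 0.0417). Of 12 root markers 3 were tested and 0 were called in either direction, also adjusted over the list alone. *ESB1* had a log2 fold change of 0.43 ± 0.30, and the median was 0.32, or -0.11 without wild type replicate 3 and 0.51 without wild type replicate 2. Of 8 floral organ genes only *PI*, a petal and stamen identity gene, was tested. It rose from 0.167 ± 0.15 to 1.38 ± 0.66 CPM (log2 3.14 ± 0.65, edgeR adjusted p = 0.0156), a call lost without wild type replicate 2 (adjusted p = 0.0740). The camera adjusted p was 0.962 for the root markers and 0.0936 for the floral list. The latter, which rests on *PI* alone, passed without mutant-labelled replicate 3 (adjusted p = 0.0270) and without wild type replicate 1 (adjusted p = 0.0215). With all libraries its adjusted p was 0.305 with an estimated correlation.

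**Figure D2:**
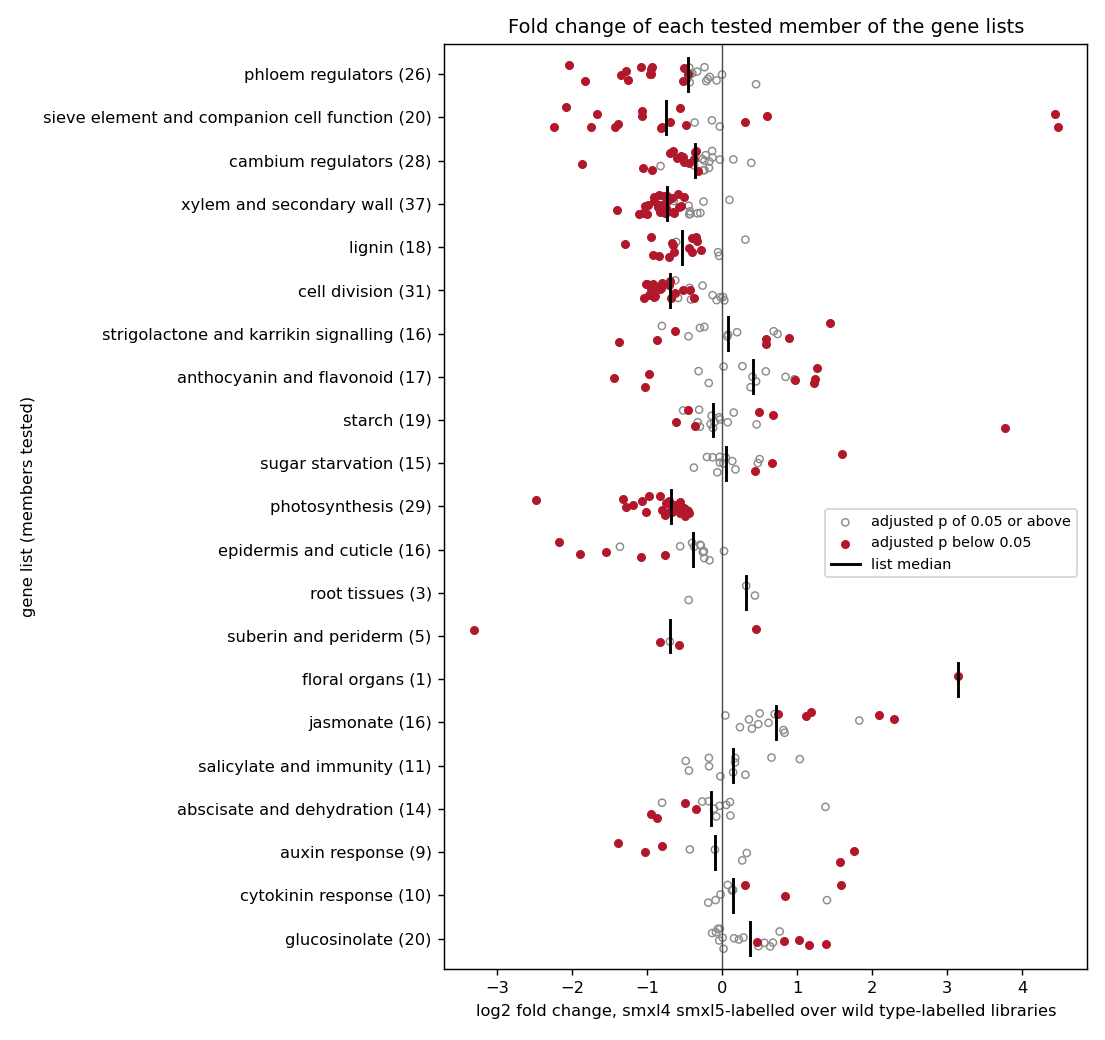
Log2 fold change, libraries labelled *smxl4 smxl5* over libraries labelled wild type, of each tested member of the 21 gene lists, with 1 row per list and the number of tested members in brackets. Filled red points passed an adjusted p of 0.05, open grey points did not, and black bars are list medians, which run from -0.76 for sieve element and companion cell function to 0.72 for jasmonate (0.37 without replicate 3 of the libraries labelled *smxl4 smxl5*) among lists of more than 1 member.

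Of 16 jasmonate genes, 5 rose and 0 fell, the same adjusted over the list alone, with a median of 0.72. *JAZ10*, a repressor induced by jasmonate, went from 36.3 ± 5.71 to 177 ± 83.5 CPM (log2 2.29 ± 0.35, edgeR adjusted p = 0.0101). *LOX2*, a lipoxygenase gene of jasmonate synthesis, went from 51.2 ± 8.07 to 218 ± 65.6 CPM (log2 2.09 ± 0.24, edgeR adjusted p = 0.00395). The camera adjusted p was 1.69e-05 at the preset correlation and the adjusted p was 0.371 with an estimated correlation. The mutant-labelled libraries differed among themselves, with mean log2 deviations of 0.16, -0.11 and 1.05 for replicates 1, 2 and 3, and 2 members rose without wild type replicate 2. Without mutant-labelled replicate 3 the median was 0.37. Of 20 glucosinolate genes, 5 rose and 0 fell, the same adjusted over the list alone, with a median of 0.37. The myrosinase genes *TGG1* and *TGG2*, whose enzymes hydrolyse glucosinolates, were among the most abundant transcripts. *TGG2* went from 3278 ± 411 to 8558 ± 1598 CPM (log2 1.38 ± 0.16) and *TGG1* from 2407 ± 268 to 5378 ± 1220 CPM (log2 1.16 ± 0.18), with edgeR adjusted p of 0.00293 and 0.00623. The camera adjusted p of this list was 0.000717 at the preset correlation and the adjusted p was 0.307 with an estimated correlation. Mutant-labelled replicate 3 stood apart here too, with a mean log2 deviation of 0.42 where replicates 1 and 2 were at 0.06 and 0.10, and without it the median was 0.15.

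The list tests for the other pathways did not pass the threshold. In strigolactone and karrikin signalling, 4 of 16 genes rose and 3 fell (4 and 5 adjusted over the list alone), among them *MAX1*, a cytochrome P450 gene of strigolactone synthesis, at 1.44 ± 0.16 and *DLK2* at -1.39 ± 0.29 (median 0.07, camera adjusted p = 0.962). In this list 2 genes rose without wild type replicate 2, and the median ran from -0.18 without mutant-labelled replicate 3 to 0.10 without wild type replicate 1. In anthocyanin and flavonoid synthesis, 4 of 17 rose and 3 fell, the same adjusted over the list alone (median 0.40, camera adjusted p = 0.161). The regulator *TT8* changed by 1.26 ± 0.31 and *PAP1* by -1.45 ± 0.22. In this list the calls changed when single libraries were left out, which also lowers the power. Without mutant-labelled replicate 2, 10 of its genes rose and the camera adjusted p was 1.23e-05. With all libraries the adjusted p was 0.724 with an estimated correlation. Without mutant-labelled replicate 1, 1 gene rose, and 0 rose without mutant-labelled replicate 3 or any wild type replicate. The median was 0.36, 0.36 and 0.43 without wild type replicates 1, 2 and 3, so those losses need not be effects of particular libraries. The number that fell was 1 without wild type replicate 1 or 2, and the median ran from 0.19 without mutant-labelled replicate 1 to 0.59 without mutant-labelled replicate 2.

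Among 19 starch genes, 3 rose and 3 fell (3 and 5 adjusted over the list alone). *GPT2*, a plastid glucose 6-phosphate translocator gene, went from 0.383 ± 0.13 to 5.38 ± 1.24 CPM (log2 3.76 ± 0.29, edgeR adjusted p = 0.00100), and the starch synthase gene *SS3* changed by 0.68 ± 0.08. The list's median was -0.13, its mean was 0.11, and its camera adjusted p was 0.973. Without wild type replicate 1 or 2, 0 starch genes fell, without mutant-labelled replicate 2, 1 fell, and without wild type replicate 3, 6 fell, with medians from -0.17 without mutant-labelled replicate 2 to -0.06 without wild type replicate 2. Among 15 sugar starvation genes, 3 rose and 0 fell, the same adjusted over the list alone (median 0.05, camera adjusted p = 0.157). The asparagine synthetase gene *ASN1* went from 30.9 ± 11.8 to 93.8 ± 21.9 CPM and the aminotransferase gene *BCAT2* changed by 0.66 ± 0.11. In this list 1 gene rose without mutant-labelled replicate 1 or 2, 1 fell without mutant-labelled replicate 3, and the list test passed without wild type replicate 1 (adjusted p = 0.0493). The adjusted p was 0.499 with an estimated correlation and all libraries. The median ran from 0.02 without wild type replicate 3 to 0.18 without wild type replicate 1.

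Of 10 cytokinin response genes, 3 rose and 0 fell (4 and 0 adjusted over the list alone), with the cytokinin synthesis gene *IPT3* at 1.58 ± 0.37 and the response regulator gene *ARR6* at 0.83 ± 0.19 (median 0.13, camera adjusted p = 0.0810). In this list 1 gene rose without mutant-labelled replicate 2 or wild type replicate 1, and 0 rose without mutant-labelled replicate 1 or wild type replicate 2. At the preset correlation the list test passed without mutant-labelled replicate 3 (adjusted p = 0.0263) and without wild type replicate 3 (adjusted p = 0.0337). With all libraries the adjusted p was 0.490 with an estimated correlation, and the median ran from 0.04 without wild type replicate 1 to 0.22 without mutant-labelled or wild type replicate 3. Of 9 auxin response genes, 2 rose and 3 fell (3 and 3 adjusted over the list alone), the risers being the auxin-conjugating enzyme genes *GH3.3* at 1.75 ± 0.29 and *GH3.2* at 1.57 ± 0.38. The median was -0.10, the mean 0.02 and the camera adjusted p 0.962. In this list 1 gene rose without mutant-labelled replicate 1 or 2 or wild type replicate 1 or 2. The median was -0.37 without wild type replicate 1, -0.34 without mutant-labelled replicate 1 and -0.24 without mutant-labelled replicate 3, but 0.20 without mutant-labelled replicate 2 and 0.23 without wild type replicate 2. Of 14 abscisate and dehydration genes, 4 fell and 0 rose, the same adjusted over the list alone, among them *COR15A* at -0.96 ± 0.23 and *RAB18* at -0.87 ± 0.20 (median -0.15, camera adjusted p = 0.186). Without mutant-labelled replicate 3, 7 fell and the list test passed (adjusted p = 0.0297, against an adjusted p of 0.456 with an estimated correlation and all libraries), 2 fell without mutant-labelled replicate 1 or wild type replicate 2, and 1 rose without mutant-labelled replicate 2. The median ran from -0.41 without mutant-labelled replicate 3 to -0.07 without mutant-labelled replicate 2. Of 11 salicylate and immunity genes, 0 rose and 0 fell, also adjusted over the list alone. *PR2* had a log2 fold change of 1.03 ± 0.43 (edgeR adjusted p = 0.132) and *WRKY70* of 0.17 ± 0.24, the median was 0.14 and the camera adjusted p was 0.962. Without mutant-labelled replicate 2 that list test passed (adjusted p = 0.0446, against an adjusted p of 0.988 with an estimated correlation and all libraries) and 2 genes rose, while 1 rose without wild type replicate 3 and 1 fell without wild type replicate 2. Its median was 0.32 without mutant-labelled replicate 2, 0.26 without wild type replicate 3, -0.01 without wild type replicate 2 and -0.23 without mutant-labelled replicate 1.

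Apart from the *SWEET* pair, the largest rises among genes with a mean of at least 1 CPM and no overlap between groups were those of *JMT*, *GASA1*, AT2G15780, *HCHIB*, *PDF1.2* and AT5G35935. *JMT*, whose enzyme makes methyl jasmonate, went from 0.203 ± 0.085 to 4.12 ± 0.72 CPM (log2 4.28 ± 0.29, edgeR adjusted p = 0.000829). *GASA1*, a gibberellin-regulated gene, rose by 4.27 ± 0.66, the cupredoxin gene AT2G15780 by 4.27 ± 0.72, the basic chitinase gene *HCHIB* by 4.25 ± 0.64, the defensin gene *PDF1.2* by 4.18 ± 0.79 and the pseudogene AT5G35935 by 4.11 ± 0.23. The mutant-labelled libraries of *HCHIB* spread from 5.02 to 19.7 CPM, above all wild type libraries, and those of *GASA1* had an SD of 27.1 around 45.2 CPM.

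The furthest falls included the pseudogene AT5G27500 (chromosome 5, 9708136 to 9709444), which had 1 count in the mutant-labelled libraries together and 450, 715 and 741 counts in wild type. The ratio of wild type to mutant-labelled reads was 1352 after scaling, with an exact 95% interval of 242 to 53448 that covers counting error only. The noncoding RNA gene AT2G01422 went from 28.8 ± 18.4 to 0.430 ± 0.076 CPM (log2 -6.09 ± 0.73, edgeR adjusted p = 0.00577). Log2 fold changes from -3.36 to -3.07 were found for *SP1L5*, a SPIRAL1-like gene, *MRD1*, the lipid-transfer-type genes AT4G15160 and AT4G22505, AT1G30250, and *HIPP21*, a heavy-metal-domain gene. *HIPP21* had the smallest SE of these (log2 -3.07 ± 0.17, edgeR adjusted p = 0.000398).

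Of 55 named genes that were called, 18 lost the call at a threshold of 0.05 under at least 1 other test, scaling, filter, block or set of libraries, namely *ARR6*, *ASN1*, AT1G30250, AT2G15780, AT4G22505, *AUR1*, *COR15A*, *DLK2*, *GASA1*, *GH3.2*, *IPT3*, *NAC045*, *PDF1.2*, *PI*, *RAB18*, *SP1L5*, *SWEET13* and *TT8*. Without mutant-labelled replicates 1, 2 and 3 in turn, 11, 5 and 1 of them lost it, and without wild type replicates 1, 2 and 3, 12, 16 and 4. Leaving out a library also lowers the power, so a lost call need not be an effect of that library. Of the 62 named loci, 10 share a near-identical stretch with another annotated locus, the nearest of which overlaps them, and their counts are uncertain to that extent. These are *KCS2*, *SS3*, *MRD1*, *ESB1*, *CDKB1;2*, *CA1*, *NAC045*, *HCHIB*, *AUR1* and *ARR6*.

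The authors' deposited table gave 5400 genes at an adjusted p under 0.05, with 2404 higher and 2996 lower in *smxl4 smxl5* once its sign, wild type over mutant, was turned. It shared 4667 calls with edgeR, all 4667 in the same direction, while 386 were called by edgeR alone and 669 of the tested genes by the authors alone. Both rest on the same counts, from which the sign was also found. A difference in direction was therefore hardly possible among shared calls. Across genes, which are not independent replicates, the fold changes of the authors' deposited table and of edgeR had a Pearson correlation of 0.944. For *SWEET11* the authors' deposited table gave -3.60 and for *DOF6* 1.72, as wild type over mutant and shrunken towards 0.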

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

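The thinned libraries were chosen only after the results were seen, and the other alternatives before the data were examined. Across all of them, 0 called genes turned direction among those also called by edgeR with its chosen settings. A turn was hardly possible among genes called both ways on the same or nearly the same libraries. The genes that lost the call are not covered by it. The number of called genes lay between 4524 and 5360 with DESeq2, limma-voom, other scaling factors, other filters, non-robust fits or libraries thinned to the smallest total. A stricter threshold of 0.01 left 1466 genes, 485 higher and 981 lower, and a minimum log2 fold change of 1 left 977, 387 higher and 590 lower. Leaving out each library in turn gave 1902 to 5558 called genes, 597 to 2423 higher and 1305 to 3135 lower. Fewer libraries lower the power, so a drop need not be an effect of the library left out. The lowest count, without wild type replicate 2, shared 1853 genes with the full set. Shifts of over 1.5 times in the higher and lower genes were found without mutant-labelled replicate 1 (1012 and 1498), without mutant-labelled replicate 2 (1512 higher), without wild type replicate 1 (884 and 1550) and without wild type replicate 2 (597 and 1305). The log2 fold change of *SMXL4* ran from 0.13 to 0.37 when single libraries were left out, and it passed the threshold without mutant-labelled replicate 3 (adjusted p = 0.0490, where the other alternatives gave up to 0.484). The cause was not tested.

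The phloem regulator list and the sieve element and companion cell list each had an adjusted p of 0.145 with an estimated correlation. For the cambium list the estimated correlation was 0.02, near the preset 0.01. Its unadjusted camera p still went from 2.44e-08 to 0.00734, so the size of the correlation alone need not be the cause. The lower degrees of freedom that camera uses with an estimated correlation also raise p. How much of the loss came from each was not tested. Under the other alternatives run without a block, adjusted p for phloem regulators lay between 6.63e-08 and 0.00189 and for sieve element and companion cell function between 1.27e-06 and 0.00274. The upper end of each range came from fry, and the rest from camera at the preset correlation. With fry, 10 lists passed directionally, while the epidermis list (adjusted p = 0.0616) and the jasmonate list (adjusted p = 0.0974) did not and the suberin (adjusted p = 0.00331) and floral lists (adjusted p = 0.0423) did. The stricter filter gave no value for 2 of the 21 lists and for 9 named genes, and thinning for 1 named gene. Of the 55 named genes that were called, 37 kept the call under each alternative test, scaling, filter, block, thinning or left-out library that gave them a value. The threshold of 0.01 and the minimum log2 fold change of 1 were not applied to named genes. In the simulation at the depth and replicate number of these libraries, 31.8% of changes of 0.5 on the log2 scale were recovered. With edgeR 181 genes were called there against 5053 in the data, so that share need not hold for the data. Thinning to the smallest library lowered the called genes to 4524.

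The counts gave no sign that replicate numbers pair the samples. Same-numbered libraries correlated between -0.02 and 0.07 in their deviations from the group means, and 1 of 6 correlated best with its own number. With 3 libraries per group these values cannot exclude a pairing. With the replicate number as a block, 3356 genes were called, 1355 higher and 2001 lower. Both phloem lists then passed camera at the preset correlation (adjusted p = 8.74e-07 for each) and fry (0.0221 for regulators, 0.0159 for sieve element and companion cell function). An estimated correlation was run only without the block, where each had a camera adjusted p of 0.145. With the block camera at the preset correlation also passed the suberin (adjusted p = 0.0477) and floral (adjusted p = 0.00354) lists. Without the block and with an estimated correlation their camera adjusted p were 0.242 and 0.305. In fry with the block, cell division (adjusted p = 0.0689) and glucosinolate (adjusted p = 0.156) no longer passed.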

Other observations

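The gene family tests, the thinning of the photosynthesis list, the test for a common fall, the summed *SWEET* counts and the test for leaf tissue were chosen only after the results were seen. Families were taken from the letters that open a gene symbol, 202 of them with at least 8 tested members. At the preset correlation of camera 25 passed, 16 lower and 9 higher, but with an estimated correlation 0 did, where 6 had an unadjusted p under 0.05 and the adjusted p was 0.889 with an estimated correlation for each family below. The median of each of the 25 kept its sign with RLE and upper-quartile factors. Among the families that passed, of 13 fasciclin-like arabinogalactan protein genes (*FLA*) 10 fell, with *FLA7* at -1.16 ± 0.14, and of 26 arabinogalactan protein genes (*AGP*) 12 fell, with *AGP4* at -1.22 ± 0.21. Among xyloglucan-modifying *XTH* genes 9 of 19 fell, and among early nodulin-like *ENODL* genes 8 of 12, with *ENODL9* at -1.39 ± 0.08. Of 28 calmodulin-binding *IQD* genes 14 fell, with *IQD10* at -1.19 ± 0.12, as did 5 of 9 beta-tubulin (*TUB*) genes, with *TUB6* at -0.69 ± 0.11.

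Other families were higher. Of 23 ribosomal *RPS* genes 12 rose and 0 fell, with a median of 0.28, and of 21 translation initiation factor (*EIF*) genes 10 rose and 0 fell, with a median of 0.24. Both families had an adjusted p of 0.889 with an estimated correlation. Among 8 genes named *NRT*, a group that holds nitrate transporters, 4 rose and 1 fell. *NRT2.5* rose by 2.06 ± 0.35 and *NRT1.5* by 1.41 ± 0.25, and this family too had an adjusted p of 0.889 with an estimated correlation. Of 13 Pumilio-type *PUM* genes 7 rose and 1 fell, with *PUM9* at 2.25 ± 0.36, and the adjusted p was again 0.889 with an estimated correlation.

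With 6 samples only 10 splits into 3 and 3 exist, too few for a share under 0.05. The genotype split called 5053 genes, and 1 of the 10 splits, the genotype split itself, gave as many. The highest count in the other splits was 0 with edgeR, where 134 to 1016 genes had an unadjusted p under 0.05. It was 38 with DESeq2 and 0 with limma-voom. Each of the other splits holds both genotypes in both groups. A genotype difference then adds to the spread within groups and lowers the calls, so these counts do not measure what chance gives.

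The photosynthesis list fell almost as a whole, with a median log2 fold change of -0.69. In the thinned libraries the median was -0.69. Thinning keeps each gene's expected share of its library, so this median could hardly move. It cannot decide whether shallower sequencing of the mutant-labelled libraries plays a part. GC content and transcript length are argued against by the median of -0.72 left after a trend on both was removed. The members did not fall alike, and 8 of 29 differed from the list's weighted mean fall of -0.73, *CA1* most of all. The 8 rest on a normal approximation with 3 libraries per group, which can overstate them. A smaller share of green tissue would give an equal fall only if all members were expressed alike in that tissue alone. That was not tested, so the spread cannot decide whether such a share is the whole cause. The cambium and xylem lists argue against it only weakly. They were lower rather than higher at the preset correlation (adjusted p = 0.145 with an estimated correlation for each). A smaller share of green tissue stays open. A lower expression of these genes with the genotype, which the counts of *SMXL4* and *SMXL5* do not check, may account for the fall, as a hypothesis found on the same data that had no test of its own.

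*SWEET11* and *SWEET12* rose while most phloem genes fell. Reads moved between related *SWEET* genes are argued against by the summed CPM of *SWEET9* to *SWEET15*, which rose by 2.94 on the log2 scale. *SWEET13* and *SWEET14* held 110 and 108 counts in wild type, and *SWEET11* and *SWEET12* held 658 and 951 in the mutant-labelled libraries. The photosynthesis median of -0.69 gave no sign of leaf tissue carried into the mutant-labelled fragments. It cannot exclude a small amount, since photosynthesis genes were already abundant in wild type stems, with *RBCS3B* at 549 CPM. Their fall, whose cause is open, could also hide such an amount, so a small amount of leaf tissue stays open. A response of sugar-exporting cells to the genotype, unchecked in the same way, may explain the rise, as a hypothesis with no test of its own, and whether more such cells or more transcript per cell are involved stays open.

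AT5G27500 was almost lost in all 3 mutant-labelled libraries, with 1 read against 1906 in wild type. A deletion that takes in the neighbouring genes is argued against by the nearest tested genes, AT5G27490 at -0.12 (3393 bases away) and *PNC2* at 0.50 (4904 bases away), neither of which passed the threshold. Reads moved to a near-identical copy are argued against by 0 stretches of at least 90% identity over 100 bases elsewhere in the TAIR10.1 genome. A smaller deletion or another sequence change of the mutant line at this locus and a loss of its transcription with the genotype stay open, since counts per gene cannot separate them.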
